A study of Mus musculus with 472 samples.

How the data were processed

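The series holds single retinal ganglion cells (RGCs), the output neurons of the retina, from C57BL/6J mice aged 7 to 9 weeks. Per the labels' protocols, each cell was patched in a flat-mounted retina, its responses to blue and green light were recorded, its content was aspirated, and the RNA was amplified with Smart-seq2, a full-length protocol without molecular identifiers. Libraries were sequenced as 150 bp paired reads, per the labels. The recordings and cell shapes were not used here. The deposited table gives estimated counts per gene and cell, which need not be whole, for 55450 genes and 92 ERCC spike-in RNAs, and 1.36% of the values were not whole. Per the submitters' processing notes, reads were aligned with STAR 2.7.0 to the mm10 build; the quantification tool and annotation release are not given in the sources used here. A deposited key pairs library names with the 472 cells, and 0 rows of the table stayed unmapped.

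Estimated counts were rounded to whole numbers first. Counts were scaled to 1000000 gene counts per cell without spike-ins (CPM), and a gene was called positive in a cell at 10 CPM or more. All 55450 gene identifiers are in GENCODE mouse release 21 on the mm10 build, which gave the 1-based positions. No cell was left out of the shares. Each sample is 1 cell and the labels name no animal, so the group of 472 cells counts as 1 sample: nothing was tested between cells and no p-value was computed. Shares carry exact (Clopper-Pearson) 95% intervals, and a share of 0 carries the limit that 3 counts allow, 0.636% of 472 cells. These limits cover counting error only, not differences between animals. No doublet caller was run, since each cell was picked singly; markers of other retinal cells were counted in their place. No pair of libraries looked like 1 library used again, the highest correlation of log2 values between 2 cells being 0.868.

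Gene counts per cell had a median of 5184792.5 and ran from 58907 to 13004880, with 7 cells under 1000000. Library names fall into 5 sequencing runs, called A (234 cells), B (98), C (62), D (59) and E (19). Names in A, D and E give a flow cell and lane, while B and C were grouped by the order number in the name. Shares of cells with sets of markers are given with their values by run or their lowest and highest run, and single genes are given pooled. Run E holds 19 cells, so its shares are coarse. The overlapping loci CT010467.1 and AY036118 on chromosome 17, which cover ribosomal RNA, took a median of 17.1% of the counts of a cell and at most 97.7%, and mitochondrial genes took a median of 0.345%.

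Before the data were examined, 26 gene lists with 265 genes were fixed. The text may name every member of lists of up to 14 genes, the 4 highest and 3 lowest members of longer lists, the 20 genes of largest excess variability and the 5 leading genes of each cluster. Excess variability is the SD of log2(CPM + 1) over cells minus the median SD of genes in the same of 20 bins of mean level, among genes positive in 10% to 90% of cells. Some genes that the rule allows, and tests that rest on them, are not reported here, and the figures leave these genes out. Genes named outside this rule were chosen after their values were seen, and are marked so. For pairs of genes, the number of cells positive for both was set beside the number expected from independent shares, pooled and summed over runs; for the pair named within a cluster the pooled number alone was used. The pairs drawn came from the fixed lists, and the pairs singled out were picked after the counts were seen.

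Cells with at least 1000 positive genes (460 cells) were clustered on log2(CPM + 1) of the 2000 most variable genes, scaled and capped at 10, with 30 principal components, 15 neighbours and Leiden resolution 1, seed 0. A cluster was named after a cell class only from the fixed markers, with at least 3 positive in 50% or more of its cells at least 1 among its 10 leading genes, and more among these than any other class had; this rule was set after a first clustering had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

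The clustering and the variability ranking were tested on simulated data with 55450 genes in 472 cells, where 200 genes were changed in 2 groups of 72 cells, 100 genes in each. With the real values of each gene shuffled between cells and nothing changed, the clustering still returned 12 clusters, so a number of clusters is no count of cell types. A 64-fold change put all 72 cells of a group in 1 cluster of 72 and all 10 leading genes were changed ones; at 16-fold 46 of the 72 cells shared a cluster, and at 8-fold 13 did. The top 200 genes by excess variability held 109 of the changed genes at 64-fold, 51 at 16-fold and 31 at 8-fold. The first version of this test used gamma-distributed noise and changes of at most 8-fold, and it failed to recover the groups: it gathered 36 of the 72 cells at 8-fold and 17 at 4-fold, and returned 10 clusters from unchanged data. The shuffled data and the 16-fold and 64-fold changes were added after that was seen; with gamma noise 64 of the 72 cells shared a cluster at 16-fold and all 72 at 64-fold. Smaller changes than 16-fold can therefore be missed by this clustering. The modularity of the partition was 0.663 in the real cells, which this test split into 9 clusters, against 0.348 in the shuffled ones. Shuffling each gene on its own also removes differences between whole cells in run, positive genes and markers of other cells. The higher value therefore does not show that ganglion cell classes part. The exact interval covered the true share in at least 94.8% of 2000 draws. Alternatives planned beforehand were positivity at 1 and at 100 CPM, thinning each cell to 1000000 gene counts without replacement, cells with at least 3000 positive genes only, CPM without mitochondrial and ribosomal protein genes, and other clustering settings; more were added later.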

Results

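Transcriptomes of single retinal ganglion cells were measured after patch recording, as 1 group with no treatment. The design implies a description: how far the patched cells carry ganglion cell genes, which class and subtype genes they carry, and which channel and receptor genes accompany a recorded cell. The median cell had 5554.5 positive genes, with quartiles of 4071.5 and 6571.75 and a highest value of 8937, at a median depth of 5184792.5 gene counts. Run medians of positive genes were 5796.5 in A, 5253.5 in B, 5608 in C, 3024 in D and 6563 in E. Of 22436 genes positive in any cell, 10796 were positive in 10% to 90% of cells and 11287 in under 10%. All values are from single cells of 1 group, and the labels name no animals.

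**Figure D1:**
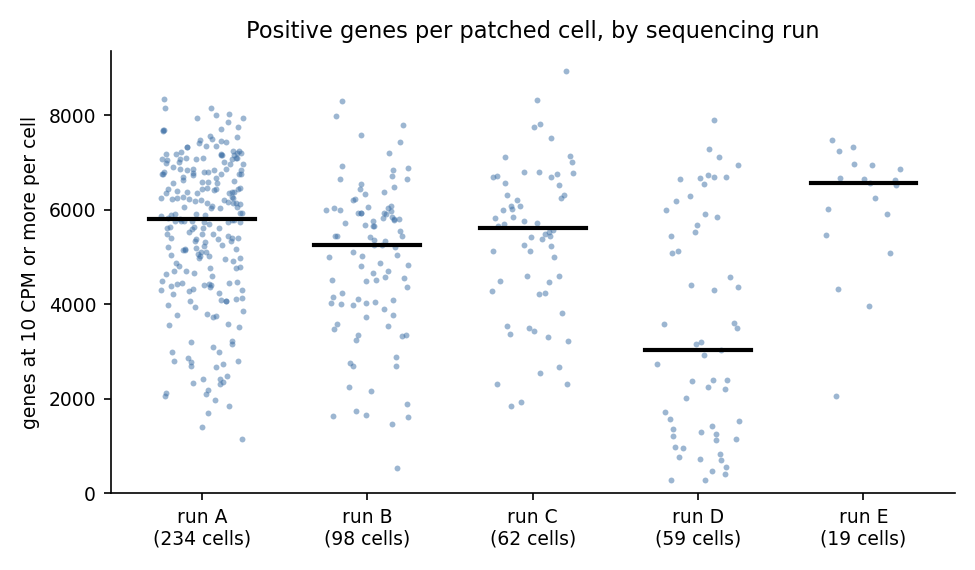
Genes at 10 CPM or more per cell (vertical axis, number of genes) by sequencing run (horizontal axis); each point is a cell and each bar the median of its run. Run D has the lowest median, 3024 genes, against 5796.5 in run A.

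Nearly all patched cells carried 6 or more of 12 listed ganglion cell (pan-RGC) genes. Nefl and Nefm, which encode neurofilament subunits, were positive in 98.5% and 96.6% of cells, Thy1 in 98.3% and Sncg in 96.2%. Slc17a6, the vesicular glutamate transporter of ganglion cells (chromosome 7, 51622006 to 51671119), was positive in 92.2% (95% interval 89.4% to 94.4%), and the RNA-binding protein gene Rbpms (chromosome 8, 33782643 to 33929863) in 89.8% (86.7% to 92.4%). Tubb3, Gap43 and Isl1 were positive in 90.5%, 80.5% and 76.9%. In all, 95.6% of cells (93.3% to 97.2%) were positive for 6 or more of the 12 pan-RGC genes. By run this share was 99.1% in A, 96.9% in B, 96.8% in C, 76.3% in D and 100% in E, and 10 of the cells below the limit, 9 of them in run D, had under 1000 positive genes. Reaching the limit does not require Slc17a6 or Rbpms. Some cells negative for both, with 3 or more amacrine markers, still reached it.

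The 3 Pou4f genes, transcription factors of sensory and ganglion neurons, differed in share. Pou4f1 (chromosome 14, 104461676 to 104467999) was positive in 81.6% of cells (77.8% to 84.96%), Pou4f2 (chromosome 8, 78433010 to 78436645) in 28.2% (24.2% to 32.5%) and Pou4f3 (chromosome 18, 42394539 to 42397249) in 24.4% (20.6% to 28.5%). Pou4f1 was the lone positive member in 42.2% of cells, it was joined by Pou4f2 in 78 cells, by Pou4f3 in 74 and by both in 34, and 61 cells were positive for none. Pou4f1 and Pou4f3 were positive together 1.15 times as often as independent shares imply, and Pou4f1 and Pou4f2 1.03 times. Pou4f3 was positive without Pou4f1 in 5 cells on its own and in 2 with Pou4f2. The intervals of 90.5 to 127.2 and 94.2 to 131.4 cells hold the 94.1 and 110.02 expected within runs. They ignore how many cells were positive for each gene and are too wide for such common genes. Whether either pair departs from independent shares cannot be told from them.

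**Figure D2:**
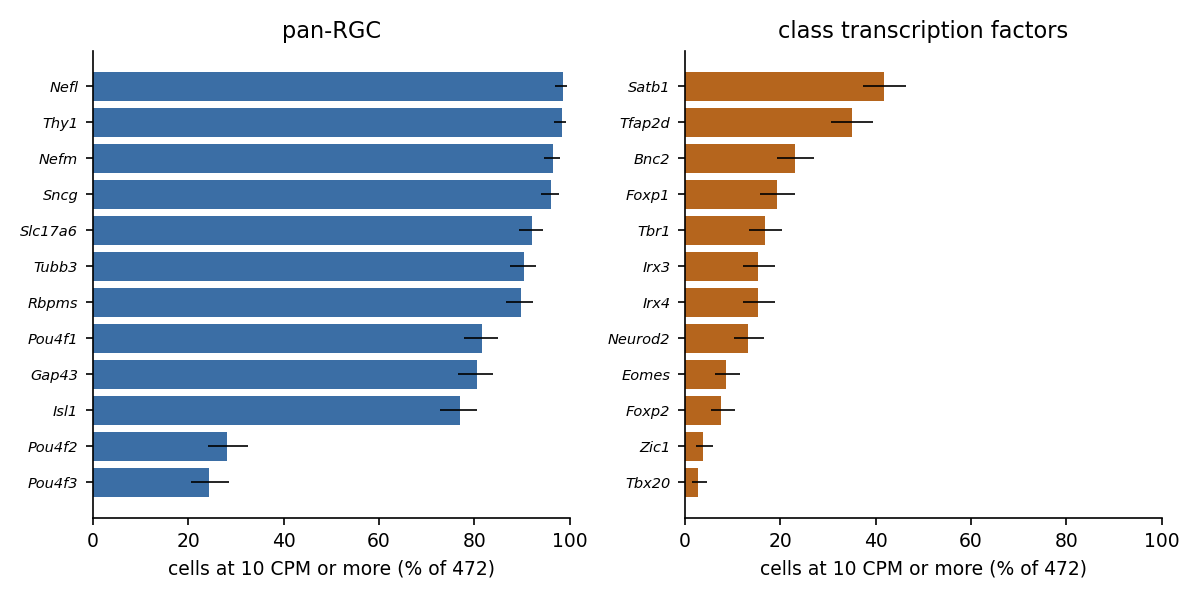
Share of all cells at 10 CPM or more (horizontal axis, percent) for the pan-RGC genes (left) and the class transcription factors (right); lines are exact 95% intervals. Nefl is highest on the left with 98.5% and Satb1 on the right with 41.7%.

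Transcription factors that part ganglion cell classes were each found in a minority of cells. Satb1 was positive in 41.7%, Tfap2d in 34.96%, Bnc2 in 23.1% and Foxp1 in 19.3%. Tbr1 was positive in 16.7% (13.5% to 20.4%), Irx3 in 15.3%, Irx4 in 15.3%, Neurod2 in 13.1%, Eomes in 8.69% (6.31% to 11.6%), Foxp2 in 7.63%, Zic1 in 3.81% and Tbx20 in 2.75%. At least 1 of Eomes, Foxp2, Tbr1, Neurod2 and Irx3 was positive in 48.9% of cells (44.3% to 53.6%; 33.9% in run D to 73.7% in run E), and 2 or more in 51 cells (10.8%, 8.15% to 13.96%), against 54.7 cells expected from independent shares. Within runs the observed and expected numbers were 25 and 25.5 in A, 9 and 12.4 in B, 8 and 8.57 in C, 6 and 4.01 in D, and 3 and 4.06 in E.

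At 10 CPM some of these factors met in the same cells more often than their pooled shares imply, and others less often. The pairs named were picked after the counts were seen, and their intervals make no allowance for the number of pairs. Eomes and Irx3 met in 13 cells (6.96 to 22.01) against 6.25 expected and 5.96 within runs. Tbr1 and Neurod2 (chromosome 11, 98325415 to 98329648) met in 4 cells (1.09 to 10.2) against 10.4 and 10.3 within runs, and Neurod2 and Bnc2 in 7 against 14.3 and 14.5. At 1 CPM the Tbr1 and Neurod2 pair was met in 25 cells against 20.6 expected. The Neurod2 and Bnc2 pair was met in 22 against 23.9, so both deficits depend on the threshold. After thinning to 1000000 gene counts the numbers were 5 against 10.6 and 9 against 14.5, nearer to the expected ones. Without cells that had 3 or more bipolar markers, Tbr1 and Neurod2 met in 4 cells against 5.19 expected. Neurod2 and Bnc2 then met in 1 against 6.67, and Eomes and Irx3 in 8 against 3.78, and these counts are small. At 100 CPM Eomes and Irx3 met in 0 cells against 0.153 expected, which is too few to tell. For the 53 pairs drawn from these factors and the subtype markers, expected numbers were pooled over all cells. The interval lay above the expected number for 20 pairs and below it for 2. These intervals ignore how many cells were positive for each gene and are too wide for common genes. A pair whose interval holds the expected number may therefore still depart from it. Cells differed widely in their number of positive genes, and pooling such cells can by itself lift the joint counts. The 20 against 2 therefore does not show that the genes of these pairs belong to the same ganglion cell classes.

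**Figure D3:**
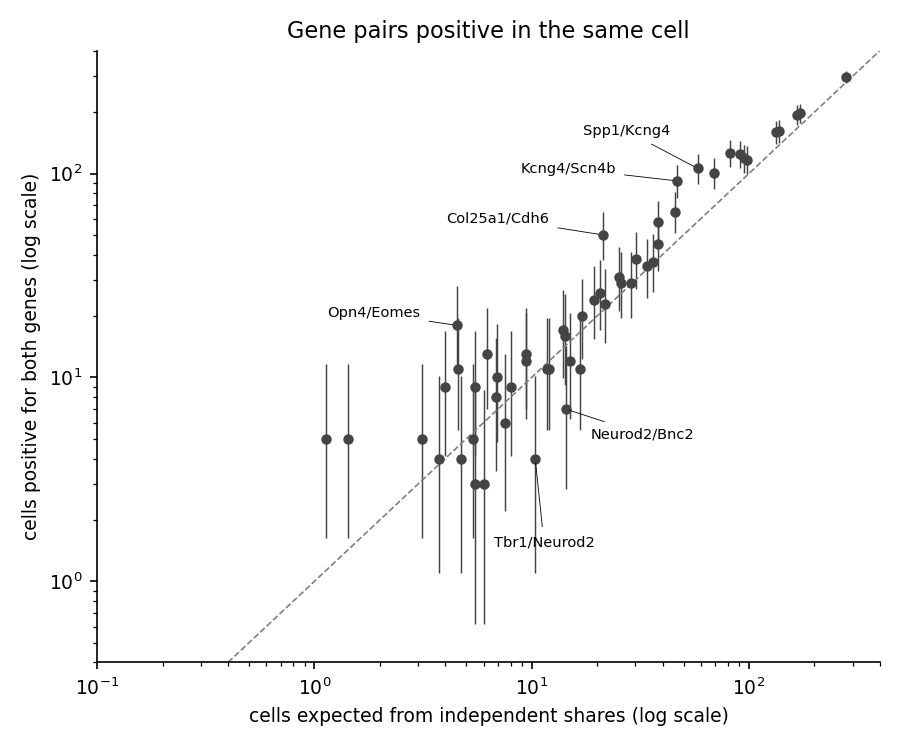
Cells positive for both genes of a pair (vertical axis, log scale) against the number expected from independent shares (horizontal axis, log scale) for 53 pairs; lines are exact 95% intervals of the observed number and the dashed line marks equality. Opn4 with Eomes lies at 18 cells against 4.52. Expected numbers are pooled over all cells, with no allowance for differences in positive genes between cells. The intervals ignore how many cells were positive for each gene.

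Markers of alpha ganglion cells were the most common of the subtype sets. Nefh was positive in 78.2% of cells, Pvalb in 76.1%, Spp1 (chromosome 5, 104435118 to 104441050) in 46.4%, the sodium channel subunit gene Scn4b in 37.3% and the potassium channel gene Kcng4 in 26.5%. Kcng4 and Scn4b were positive together in 92 cells against 46.6 expected and 55.1 within runs, and Spp1 and Kcng4 1.83 times as often as their shares imply, with an interval of 88.6 to 125.06 cells against 65.1 within runs. In all, 49.4% of cells (44.8% to 53.97%) had 3 or more of the 5 markers, 66.7% in run A and 25.8% in run C, so this share differed between runs. Nefh and Pvalb, each in over 75% of cells, lift it.

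Direction-selective and melanopsin markers gave smaller sets. Of the ooDSGC (ON-OFF direction-selective) markers, Cartpt was positive in 58.9%, Cdh6 in 32.6%, Col25a1 in 13.8% and Mmp17 in 6.14%, and 50 cells (10.6%, 7.97% to 13.7%; 6.12% in run B to 13.2% in run A) had 3 or more. Col25a1 and Cdh6 met in 50 cells against 21.2 expected and 20.996 within runs. Opn4, which encodes melanopsin (chromosome 14, 34590618 to 34600142), was positive in 11.02% of cells and reached 5645 CPM. Opn4 and Eomes met in 18 cells (10.7 to 28.1) against 4.52 and 4.67 within runs, while 4 cells (0.847%, 0.231% to 2.16%; 0% in runs A and C to 5.26% in run E) had 3 or more ipRGC (intrinsically photosensitive ganglion cell) markers. Adcyap1 was positive in 28.8% of cells and met Opn4 in 12 against 14.98 and 14.8 within runs. Of the F-RGC markers Coch was positive in 39.6%, and 16 cells (3.39%, 0% in runs D and E to 8.06% in C) had 3 or more. Coch was not particular to this set: in the 72-cell alpha-like cluster described below it was positive in 90.3% and Foxp2 in 1.39%. Of the T-RGC markers Jam2 was positive in 42.8%, Sorcs3 in 10.2% and Cdh8 in 9.53%. In 13 cells (2.75%, 0% in run D to 15.8% in E) 3 or more T-RGC markers were positive.

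Several channel genes were positive in most of the patched cells. Among sodium channels Scn1a was positive in 93.4% (90.8% to 95.5%), Scn2b in 88.6%, Scn8a in 85.6% and Scn2a in 77.8%. Scn11a was positive in 2 cells and Scn10a, a channel gene of sensory neurons, in 0 cells, which allows a share of up to 0.636%. Kcnc1, which encodes a fast delayed-rectifier potassium channel, was positive in 88.6%, Kcnip4 in 82.4% and Kcnc2 in 79.7%, while Kcnn3, Kcnk2 and Kcnq5 were positive in 3.60%, 3.18% and 2.33%. Of the calcium channel genes, Cacna1b was positive in 44.7%, Cacna1a in 42.8% and Cacna1e in 7.63%. In these lists 6 of 13 sodium, 15 of 30 potassium and 1 of 13 calcium and HCN channel genes were positive in 50% or more of cells.

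In the receptor lists, 7 of 24 glutamate, 5 of 22 GABA and glycine, and 3 of 18 acetylcholine and dopamine receptor genes were positive in 50% or more of cells. Gria2 and Grin1, subunits of AMPA and NMDA receptors, were each positive in 86.4% (83.02% to 89.4%), Gria4 in 79.9% and Gria3 in 66.3%, against 2.12% for Grm3 and 0.636% for Grin2c and for Grin3b. For inhibition, Glrb was positive in 80.7% and Gabra6 in 0 cells, which allows up to 0.636%. Chrna6 (chromosome 8, 27403212 to 27413944) and Chrnb3, nicotinic acetylcholine receptor subunits, were positive in 90.04% and 88.1%, Chrnb2 in 75% and the dopamine receptor gene Drd1 in 45.1%, while Chrna5 was positive in 1 cell. The gap junction list also holds pannexin genes, of which Panx2 was positive in 43.01% and Panx1 in 29.2%. Of its connexin genes, Gjd2 was positive in 21.2% and Gjd4 in none. Over the channel, receptor and gap junction lists together, 37 genes were positive in 50% or more of cells. These pooled shares do not hold in every cluster: in a cluster of 57 cells with few positive genes Scn1a and Chrna6 were positive in 71.9% and 73.7%, but Scn2a in 35.1%, Kcnc2 in 42.1%, Gria2 in 40.4% and Chrnb2 in 26.3%. In 2 alpha-like clusters of 72 and 30 cells, Scn2a was positive in 84.7% and 33.3%, and their median cells had 6578 and 3959 positive genes. RNA of other retinal cells may also enter the pooled shares, which cannot set it apart. In a cluster of 50 cells led mostly by photoreceptor genes, Grm6 and Cacna1f were positive in 66% and 72%, and Scn1a in 98%. In the 72 alpha-like cells these shares were 4.17%, 8.33% and 100%. These genes were picked after their values were seen.

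**Figure D4:**
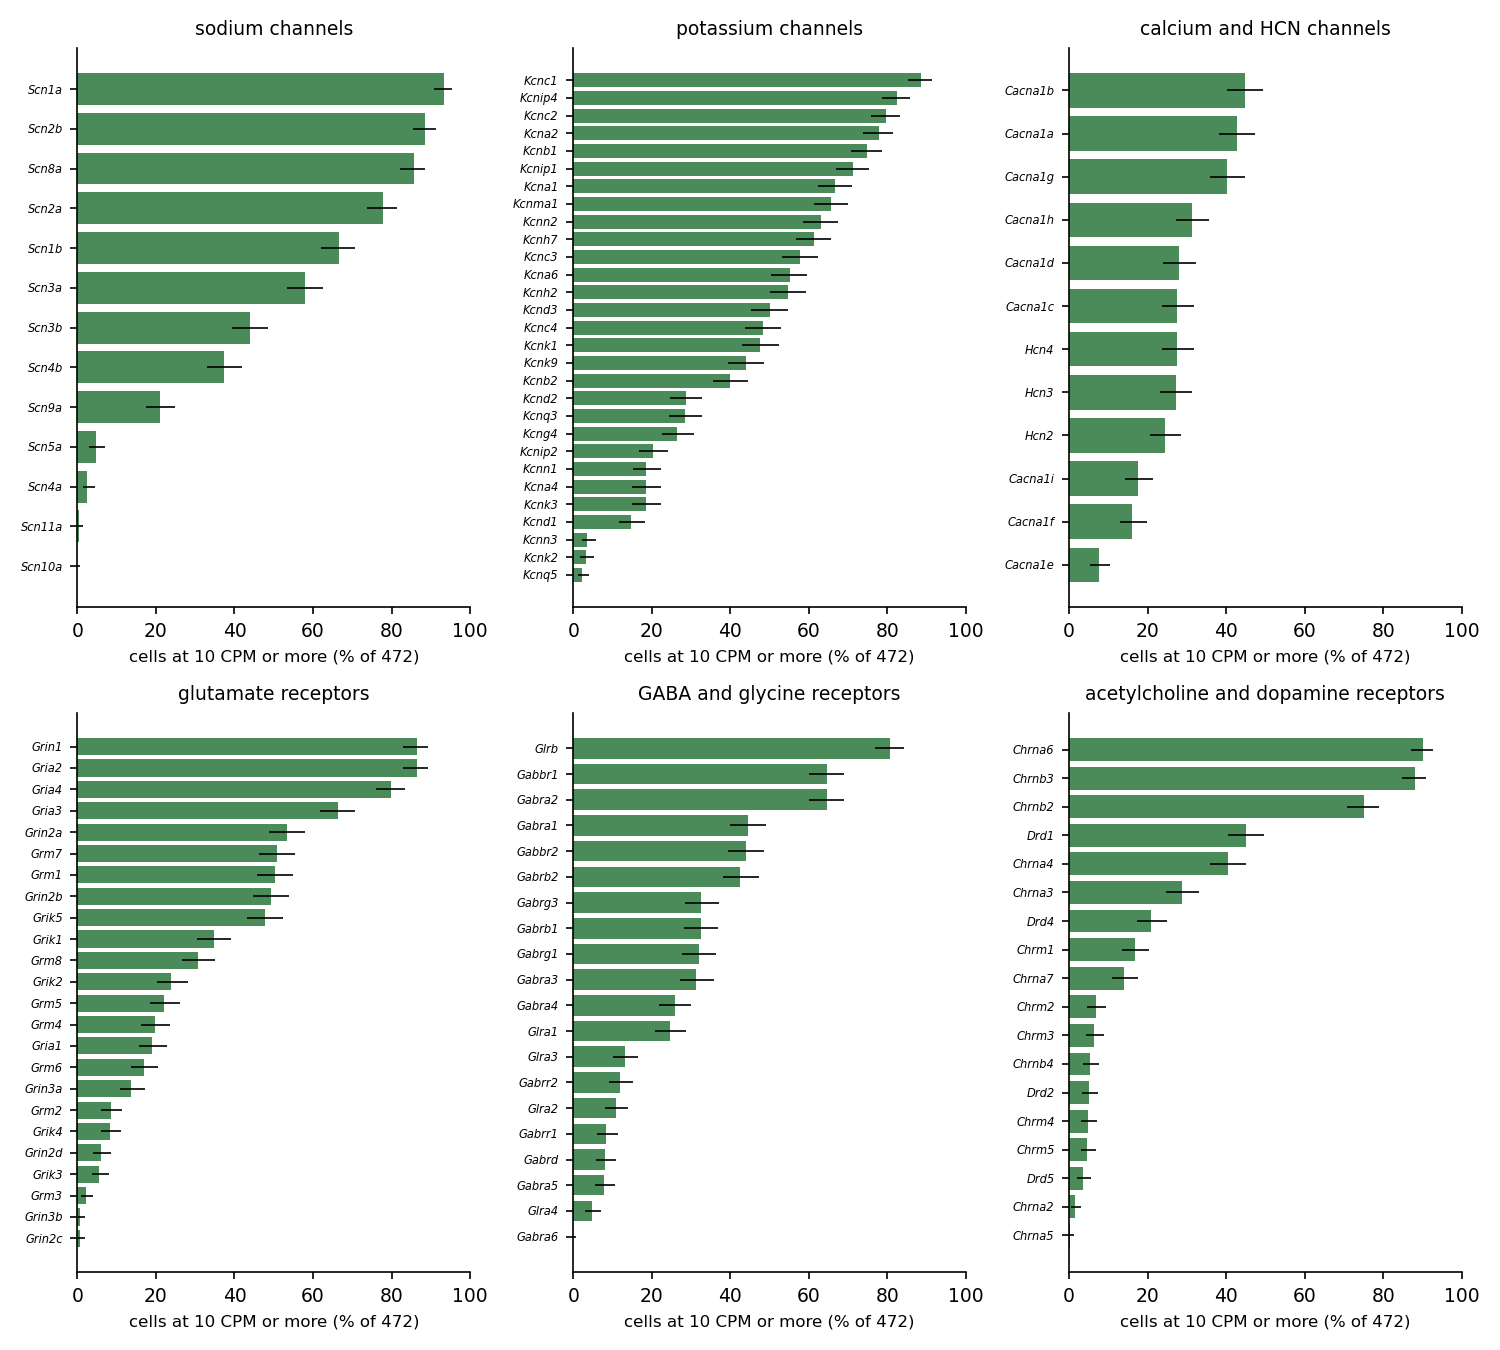
Share of all cells at 10 CPM or more (horizontal axis, percent) for channel and receptor genes in 6 lists; lines are exact 95% intervals. Scn1a is highest among sodium channels with 93.4% and Chrna6 among acetylcholine and dopamine receptors with 90.04%.

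Genes of other retinal cells were found beside ganglion cell genes. The rod genes Gnat1 and Sag, which act in the light response, were positive in 66.9% and 60.8%. At least 3 markers were positive in 61.2% of cells for rods (53.2% in run C to 94.7% in E), 31.4% for bipolar cells (20.3% in D to 78.9% in E), 26.5% for amacrine cells (18.6% in D to 57.9% in E) and 10.4% for cones (6.12% in B to 31.6% in E). For astrocytes the number of cells was 7, for microglia 14, for vessels 5 and for erythrocytes 22, in no run above 4.84%, 5.08%, 5.26% and 10.5%. Müller glia markers reached 79.4% of cells (61.02% in D to 89.5% in E), led by Clu in 91.1%, Glul in 82.6% and Dkk3 in 78.6%. At least 1 of these types was met in 90.04% of cells (86.98% to 92.6%; 83.1% in D to 94.7% in E), and in 68.9% when Clu, Glul and Dkk3 were left off the Müller list, a choice made after the values were seen. The lowest of the 8 Müller markers was positive in 12.3%. In the 72-cell alpha-like cluster described below, Clu, Glul and Dkk3 were positive in 97.2%, 90.3% and 95.8%. There Apoe, Rlbp1, Aqp4, Slc1a3 and Sox9 were positive in 56.9%, 34.7%, 11.1%, 6.94% and 5.56%. The 79.4% therefore cannot be read as the share of cells with Müller glia RNA. Of the cells with 3 or more amacrine markers, 3 had under 6 pan-RGC genes and 6 were negative for both Slc17a6 and Rbpms, 5 of these in run C (8.06% of that run).

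Unsupervised clustering gave 8 clusters over 460 cells, none of them a single run. A cluster of 72 cells was alpha-like: Spp1, Scn4b, Gm43175, Coch and Slitrk6 led it, all 5 alpha markers were positive in 50% or more of its cells, and 58 of the 72 cells came from run A. A cluster of 30 cells, led by Spp1, Ctxn3, Kcng4, Nefh and Coch, also met the alpha-like rule, with 26 cells from run A; its median cell had 3959 positive genes and a spike-in share of 1.54%, against 6578 and 0.526% in the 72 cells. A cluster of 50 cells was led by Prph2, Pde6b, Rbp3, Kcnj14 and Sag, mostly photoreceptor genes, but markers of other cells were common in it too: the median marker was positive in 79% of its cells for bipolar cells, 55% for cones and 50% for amacrine cells. In the other clusters these values were at most 25.4%, 9.52% and 20.6%. The naming rule calls this cluster rod-like, but its median cell had 10 of the 12 pan-RGC genes, so no class is named for it here, a departure from the rule made after the values were seen. The other clusters stayed unnamed: 63 cells with Hpcal4, Pkia, Caln1 and Kctd8 among the leading genes; 63 by Pcdh8, Cntn4, Atp8a1, Nell1 and Chrna3; 42 by Fam163a, Htr1d, Mmp9, Pcdh8 and Rasd2; 83 by A330076H08Rik, Gm43670, 9330162G02Rik, Leng8 and Srsf2; and 57, with a median of 2169 positive genes, by mt-Rnr2, Tmsb10, AY036118, mt-Rnr1 and CT010467.1. The 5 leading genes differed in mean log2(CPM + 1) from the other clustered cells by 1.115 to 1.391 in the 83 cells. In the 57 cells the differences were 0.546 to 1.031, against 4.635 to 6.96 in the 72 alpha-like cells. Tmsb10 was positive in 82.5% of the 57 cells and in 86.8% of the others, so it does not mark this cluster. Over 16 alternative settings the median overlap (Jaccard index) of the closest cluster was 0.986 for the 72 cells, 0.838 for the 50 cells, 0.594 for the 30 cells, 0.536 for the 83 cells and 0.655 for the 63 cells led by Pcdh8, so the last 3 are not stable. For the 63 cells with Hpcal4 it was 0.866, for the 42 cells 0.848 and for the 57 cells 0.767, with lowest values of 0.310, 0.266 and 0.375.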

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

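The ERCC spike-in RNAs, which none of the shares of genes and markers uses, were flagged because their share of all counts rose far above the limit that a count of 0 allows. The share reached 31.1% in a cell of run D with 547 positive genes, against a median of 0.738% over all cells. It was above 5% in 31 cells, of which 17 were in run D, where the median was 1.94%. The amount of spike-in added per cell is not given in the sources used here.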

How the results depend on the processing

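Most share results moved with the threshold that calls a gene positive and little with depth. For shares and the median of positive genes, the interval of the main value served as the yardstick. For the numbers of clusters and of channel and receptor genes positive in 50% or more of cells, it was a fixed fold range around the main number. That range ignores which cells group together. At 1 CPM the median of positive genes was 6794.5 and shares were 98.3% for 6 or more pan-RGC genes, 95.3% for any other cell type, 59.5% and 21.8% for at least 1 and for 2 or more of Eomes, Foxp2, Tbr1, Neurod2 and Irx3, and 3.39%, 66.1%, 8.69%, 16.7% and 6.99% for 3 or more ipRGC, alpha, F-RGC, ooDSGC and T-RGC markers. At 100 CPM the same values were 2054 genes, 86.4%, 61.02%, 10.2%, 0.212%, 0.212%, 25%, 0%, 3.18% and 0.212%, and the channel and receptor genes positive in 50% or more of cells fell from 37 to 12. With only the cells of at least 3000 positive genes the median was 5849, the pan-RGC share 98.7% and the share with another cell type 92.98%. The alternatives added after seeing the data were CPM without the ribosomal RNA loci, which gave a median of 5765, the cells without run D, which gave a pan-RGC share of 98.3%, the Müller list without Clu, Glul and Dkk3, which gave 68.9%, and clusterings without run D, without Rn7s1, Rn7s2, the ribosomal RNA loci and Xist, in deposited cell order and with 3 other seeds. The number of clusters was 4 at resolution 0.5 and 15 at resolution 2, and 7 or 8 in the other 14 clusterings. Cell membership moved even with the seed alone (adjusted Rand index 0.844 to 0.864 over 3 seeds), and further with other settings: the index was 0.463 at resolution 0.5, 0.573 at resolution 2, 0.508 with median-of-ratios size factors, 0.578 with a pseudocount of 10 and 0.622 with 1000 variable genes. The remaining alternatives for these results, 65 of 94, stayed inside the yardstick. They include thinning to 1000000 counts and, whatever their cell membership, the 14 clusterings with 7 or 8 clusters. Of the 64 alternatives for the other results, 45 stayed inside the yardstick and 19 moved. Apart from the thresholds and cell sets, which change what is counted, the cause of these moves was not tested. No paired analysis was possible because the cells form 1 group.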

Other observations

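Some activity genes were common in the patched cells and others were not. Fos was positive in 86.4% of cells (83.02% to 89.4%) with a median of 445.9 CPM, Egr1 in 76.9%, Junb in 68.6% and Jun in 66.5%. Arc, Npas4 and Nr4a1 were positive in 14.4%, 19.5% and 23.7%, and 6 of the 15 genes of the activity and injury list were positive in over 50% of cells. The injury gene Ecel1 was positive in 0 cells, which allows up to 0.636%, Hspa1b in 2.54% and Atf3 in 9.75%, but Ddit3 was positive in 53.6% and Sox11 in 39.6%. Arc, Npas4, Nr4a1, Ddit3 and Sox11 were added after their values were seen. Among subtype candidates Calb2 was positive in 91.7%, Calb1 in 53.6%, Igf1 in 44.9% and Cck in 26.3%, and Postn in 2 cells. The horizontal cell genes Onecut1, Onecut2 and Lhx1 were positive in 17.6%, 15.9% and 2.75%.

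The genes of largest excess variability were led by Rn7s2 and Rn7s1, near-identical copies of a small cytoplasmic RNA gene, positive in 16.3% to 100% and 17.3% to 100% of cells between runs. Gnat1, Sag, Prph2, Pde6g and Pde6b, all photoreceptor genes, were among the 20, as were Spp1, Coch, Ctxn3, Calb1, Fgf1, Rgs11, Zmat4, Apoe, Gm43670 and 5031439G07Rik. In the 72-cell alpha-like cluster Fes was positive in 38 cells, Opn4 in 15, Il1rapl2 in 13, Tpbg in 9 and Kit in 1; Il1rapl2 and Opn4 met in 9 cells against 2.71 expected. These 5 genes were chosen after values were seen.

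The tests of shallow sequencing and RNA yield were chosen after the results were seen. Those of the transcription factors, Xist and Cryaa were written before their values were computed, but the Xist and Cryaa patterns, and the Y-linked and lens genes used for them, were picked after the variability ranking had been seen. Class transcription factors positive together could come from RNA of other retinal cells. Without the cells with 3 or more bipolar markers, 31 cells had 2 or more of the 5 factors against 30.7 expected, a ratio of 1.01 (0.695 to 1.40), and the width of this interval keeps the explanation open. No biological explanation of this pattern was tested.

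The 57-cell cluster with few positive genes is not explained by shallow sequencing alone. Its median depth was 4505671 gene counts against 5321235 in the other clustered cells, and its median of positive genes 2169 against 5841. After thinning to 1000000 counts its median was 37.6% of that of the others, but with such similar depths thinning could change little. A low RNA yield from the aspirate is a candidate explanation. The median spike-in share of the 57 cells was 4.62 times that of the others, 2.95% against 0.639%, and higher in each of runs A to D. Run D gave 22 of the 57 cells.

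As a hypothesis, cells from both sexes may lie behind Xist, positive in 37.1% of cells and in 0% to 57.9% of a run. Of the Xist-positive cells, 0% had 2 or more of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d (limit 1.71%), as the test asked. Of the cells without Xist 57.6% did, short of the 80% that the test asked for, and the rest of them had neither. In run C 0% of cells were positive for Xist and 77.4% for 2 or more Y-linked genes, against 45.8% and 8.47% in run D. The 2 signals thus never met in a cell. By its own rule the test leaves the hypothesis open, but only because of the cells with neither signal. Such cells give no sign of either sex, so they do not argue against it. Cryaa, a lens crystallin gene, may reflect lens RNA: in the 34 cells with Cryaa at 1000 CPM or more, the median cell was positive for 4 of 5 other lens genes. The crystallin genes Cryab, Cryba1, Crybb2 and Crygs were positive in 97.1%, 94.1%, 100% and 100% of these cells, but Mip in 35.3%. Over all cells the 5 shares were 35.2%, 20.97%, 25.2%, 20.3% and 4.24%. Other sources of these transcripts were not tested.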
